A study of Drosophila melanogaster with 12 samples.

How the data were processed

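Polyadenylated RNA of salivary glands and wing imaginal discs of L3 larvae had been sequenced in 12 libraries, 3 in each of 4 groups: control glands, mutant-labelled glands, control discs and mutant-labelled discs. The tissues differed in the mRNA enrichment as well, so library preparation and tissue coincide in every comparison between them. Each library has a table of genes and a table of transposable elements. The gene tables deposited hold counts per FlyBase gene ID, which are whole numbers with a different total in every library, and the labels name cutadapt, HISAT2 and featureCounts and the builds BDGP6 and dm6 for them, with no version, order or option. The transposon tables deposited hold an estimated count of reads per element consensus, not scaled to depth, and the tool (SalmonTE) is known from the file names alone, its version, reference and options not being given in the sources used here. No column of either kind was left out. In 3 control libraries, 4 cells of the transposon tables (0 in the other libraries) hold month names in place of numbers, so the elements concerned were left out of the fits of that tissue unless stated.

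Of 17807 gene IDs, 17710 had a model in the annotation (release 115), and 97 had none and keep their ID. Depth was 17418224 to 57591665 gene counts per library, and 3 counts came to 0.0521 to 0.172 CPM. The biological coefficient of variation was 0.292 in glands and 0.102 in discs, which includes only whatever variation the replicates hold. Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15.

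Within each tissue, genes were kept by filterByExpr with its default settings, libraries scaled by TMM factors, and mutant-labelled compared with control libraries by edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The difference of the changes between the tissues was the interaction term of a fit to all 12 libraries (discs minus glands). That fit shares its spread between the tissues, although glands varied more. A prior count of 2 was used only for the log2 CPM of the list tests and of the comparison of replicate numbers. Log2 changes of the fits use edgeR's default prior, which is smaller, and CPM use none. SE is the log2 change without a prior, divided by the square root of the F of its test. It is thus worked back from the test, and it can be too small for steep changes where a group has few counts. SD is between libraries. A fold against a group without a count was computed against a floor of 3 counts over the group. Transposon counts were rounded and fitted in the same way with the effective library sizes of the genes, so that a change is relative to gene reads. The sum over elements was compared by an exact permutation test, two-sided.

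Before the data were examined, 45 gene lists, the alternatives and the rule for naming genes were fixed. Lists with at least 3 members tested were compared with the other genes by camera with a preset correlation of 0.01, with camera and an estimated correlation, and with fry, which asks whether a list's genes move one way on balance and compares them with no other genes. The lists described are antimicrobial, detoxification, fat-body, tracheal, wing-patterning, glue, early ecdysone-response, heterochromatin-factor, piRNA-pathway, pericentromeric and chromosome 4 genes in glands. In discs they are cytosolic ribosomal, piRNA-pathway, ovarian, wing-patterning, replication, secretory, endocycle, homeotic and Polycomb-target, oxidative-phosphorylation, heat-shock, disc-marker, ecdysone-response, hemocyte, cuticle, JNK, heterochromatin-factor and pericentromeric genes. Which lists to describe was chosen after their results were seen. Calls per chromosome arm, chromosome 4 and the pericentromeric regions were compared with those elsewhere by Fisher's exact test, two-sided, adjusted over the regions of a tissue.

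Genes named are egg, Su(var)3-9 and eIF2gamma, then per tissue the 8 largest rises and the 8 largest falls among genes past the threshold whose groups do not overlap and whose higher group averages at least 10 CPM, up to 4 members of each list described with the lowest p, and roX1 and roX2. For the difference between tissues these are 5 genes in each direction, and for both tissues the 5 in each direction with the largest smaller change. For elements they are the 5 largest changes in each direction per tissue, and HeT-A, TART, TAHRE, gypsy, copia, roo, 412, 297, 1731, mdg1, R1 and R2. The rule gave 61 genes in glands and 84 in discs, 139 in all, not every one of which is described.

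The alternatives were RLE and upper-quartile factors, no low-count filter, DESeq2, limma-voom, a block of replicate numbers, the 20 most abundant genes removed, all 12 libraries fitted together for the tissue comparisons, a log2 change of at least 1, transposon totals as library sizes, genes within 1 Mb of egg and Su(var)3-9 left out, and each library left out in turn. Counts under other splits of the libraries were made for every such comparison. The procedure was tested on simulated data with the observed dispersions: 25.4% of 2-fold changes were recovered in glands, 100% in discs and 16.4% for the difference between tissues, 100%, 100% and 95.5% of 4-fold changes, and 6.92%, 8.68% and 8.50% of the calls were false against a nominal 5%. For transposable elements 5.56%, 4.76% and 8.82% of the calls were false. Simulated changes were placed in genes that were not of the lowest abundance. They were made in 1 run and in few genes (at 2-fold, 67 of 9298 in glands), a smaller share than was called in the data. Recovery and the share of false calls depend on that share, so these values may not carry over to the data. GC content was not examined, since no genome sequence was at hand.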

Results

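RNA was sequenced from salivary glands and wing imaginal discs of Drosophila melanogaster larvae at stage L3, to ask how each tissue's transcripts differ when a pair of H3K9 methyltransferases is mutated. In each tissue, 3 libraries came from Oregon R controls and 3 were labelled as knock-out (KO) mutants for both egg (SetDB1) and Su(var)3-9. Each library was made from 25 glands or 25 disc pairs. Gene counts came to 19775440, 17418224 and 52209922 in control glands and 57591665, 54719736 and 43909478 in mutant-labelled glands. They came to 22119529, 19781382 and 27303075 in control discs and 23337165, 28136399 and 23818750 in mutant-labelled discs. The 20 most abundant genes took 40.7% to 46.0% of the counts in glands and 10.02% to 12.3% in discs. Changes are given as log2 of mutant-labelled over control ± SE, levels as normalized CPM, mean ± SD, with n = 3 libraries in each group. The labels mention technical replicates, so the p-values may measure only technical spread between libraries. Between libraries of a group, chi-square per gene was 94.9 to 310 in glands and 4.40 to 39.1 in discs. This is beyond sampling noise and argues against resequencing of the same library. It leaves open whether the libraries came from separate animals. No strand-marking kit is named in the sources used here, so counts of genes that overlap another gene are uncertain.

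Su(var)3-9 (FBgn0263755, chromosome 3R, 15259864 to 15263458, BDGP6), which encodes an H3K9 methyltransferase, moved in opposite directions in the 2 tissues. In mutant-labelled discs it was 6.29-fold lower (25.0 ± 0.600 to 3.98 ± 0.801 CPM; log2 -2.65 ± 0.14, adjusted p = 4.46e-07). In mutant-labelled glands it was 32.7-fold higher (2.48 ± 0.431 to 81.1 ± 27.1 CPM; log2 5.04 ± 0.31, adjusted p = 8.73e-05), in 3 of 3 libraries above all controls, which is against the label of those libraries. The difference between the changes was itself past the threshold (log2 -7.77 ± 0.32, adjusted p = 4.15e-08). Groups are therefore called mutant-labelled throughout, and every direction in glands rests on that label. egg (FBgn0086908, chromosome 2R, 24775534 to 24779901, BDGP6) passed in neither tissue (7.80 ± 2.49 to 7.30 ± 0.476 CPM in glands, adjusted p = 0.851; 136 ± 5.63 to 132 ± 6.49 CPM in discs, adjusted p = 0.699). The label names a knock-out of egg, which these levels do not show. What the egg allele does to the transcript is not given in the sources used here, so the levels neither bear out nor contradict the label. eIF2gamma, an initiation factor whose exons overlap 14.8% of the exons of Su(var)3-9, changed by 0.11 ± 0.18 in glands and 0.14 ± 0.062 in discs (adjusted p = 0.761 and 0.122). Of egg's exons, 16% overlap an antisense RNA, asRNA:CR44067. The male-specific lncRNA:roX1 passed in neither tissue (-1.24 ± 0.85 in glands, adjusted p = 0.403; 0.48 ± 0.43 in discs, adjusted p = 0.432). lncRNA:roX2 did not pass in glands (1.08 ± 0.75, adjusted p = 0.411) and had too few counts to be tested in discs.

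**Figure D1:**
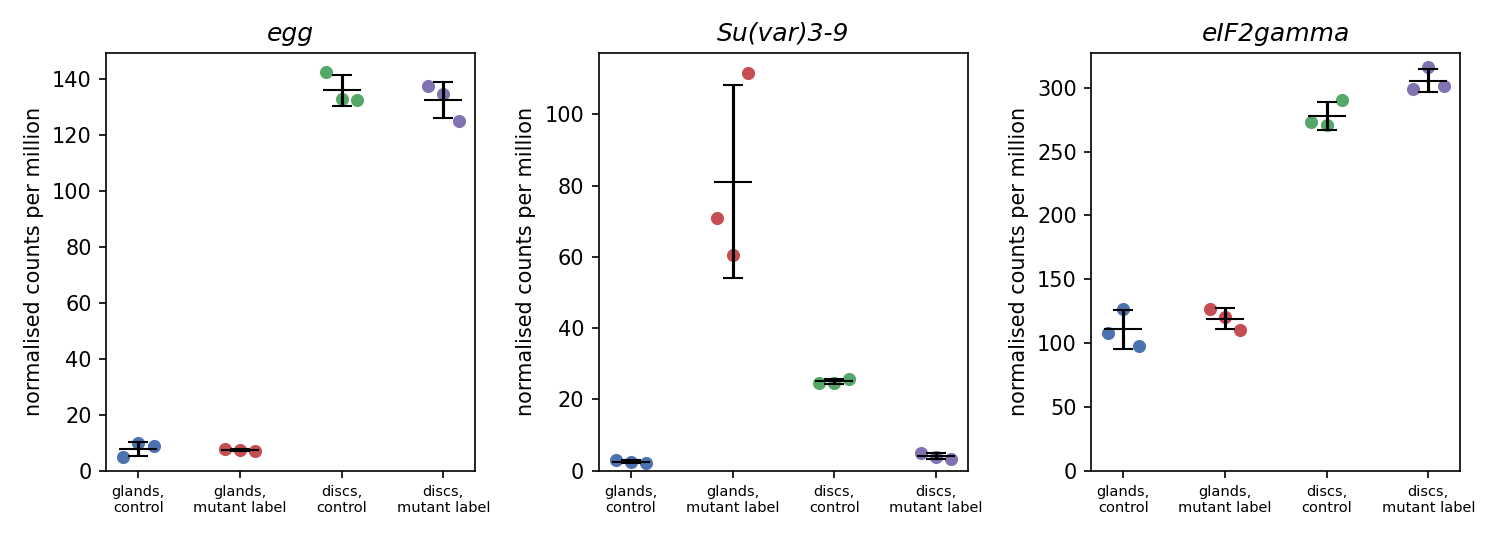
Levels of egg, Su(var)3-9 and eIF2gamma in each library, in normalized CPM. Each point is 1 library, horizontal lines are group means and error bars are SD over n = 3 libraries per group.

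In mutant-labelled glands, genes for short immune peptides of the Bomanin family rose: BomS1 57.3-fold (1.39 ± 0.884 to 79.9 ± 12.4 CPM; log2 5.89 ± 0.44, adjusted p = 0.000189), BomS2 55.3-fold, BomBc1 51.8-fold and BomS3 38.9-fold (adjusted p of these 3 at most 0.000176). bcd, the maternal determinant of the embryo's anterior, rose 50.5-fold (0.240 ± 0.238 to 12.1 ± 8.54 CPM; log2 5.93 ± 0.81, adjusted p = 0.00309). Among the steepest falls were those of Jig (170.4-fold lower, 413 ± 193 to 2.42 ± 0.448 CPM; log2 -7.41 ± 0.44, adjusted p = 7.99e-05), phu (153-fold lower), and GluRIIC, a glutamate receptor subunit of the neuromuscular junction (144-fold lower; adjusted p at most 7.99e-05). The other large rises were of CG3635 (6.59 ± 0.36), Grik (5.87 ± 0.37), lncRNA:CR45473 (5.54 ± 0.33) and alpha-Est1 (5.46 ± 0.39). The other large falls were of lncRNA:CR45043 (-7.20 ± 0.75), Drsl5 (-6.94 ± 0.80), mthl8 (-6.81 ± 0.41), CG33099 (-6.16 ± 0.43) and CR44383 (-5.85 ± 0.36); the adjusted p of all 9 was at most 0.00137. Of 9441 genes tested in glands, 1243 (13.2%) passed an adjusted p of 0.05 with edgeR's quasi-likelihood test, 685 higher and 558 lower, and 2527 had an unadjusted p under 0.05. Among the 1243, 1033 changed by at least 1 on the log2 scale. The count was 710 without control library 1, 726 without control 3, 798 without mutant-labelled 1 and 705 without mutant-labelled 2, and 2360 when all 12 libraries were fitted together. Single libraries moved the log2 change of BomS1 (6.51 without control 2) and bcd (7.08 without control 1, 5.15 without control 3, less far without mutant-labelled 3) by over 1.5 times (as a fold, here and below).

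Antimicrobial genes of mutant-labelled glands changed in both directions. With the Bomanins rose Drs, a Toll-induced antifungal peptide (4.77 ± 0.47). The antibacterial peptide genes DptB (-5.36 ± 0.48) and CecA1 (-3.001 ± 0.57) and the amidase PGRP-SC1a (-5.29 ± 0.98) fell (adjusted p of these 4 at most 0.0122). In all, 9 rose and 11 fell of 40 tested (11 and 11 adjusted over the list alone). As a list, antimicrobial genes had a camera adjusted p = 0.710 (adjusted p = 0.997 with an estimated correlation). Their median was -0.38 and their mean -0.10, with camera downward and fry upward. Of detoxification genes, 14 rose and 1 fell of 44 tested (19 and 2 adjusted over the list alone). The glutathione transferases GstE1 (3.81-fold, log2 1.93 ± 0.25) and GstE10 (3.95-fold) and the cytochromes P450 Cyp6a17 (23.5-fold) and Cyp12d1-p (12.4-fold) led them (adjusted p at most 0.00273). As a list, detoxification genes had a camera adjusted p = 0.000599 (adjusted p = 0.869 with an estimated correlation). The fat body also makes many immune and detoxification transcripts, and some of its own markers rose too. Of these, 6 rose and 0 fell of 16 tested (8 and 0 adjusted over the list alone). As a list, fat-body markers had a camera adjusted p = 0.000599 (adjusted p = 0.869 with an estimated correlation). Among them were the larval serum protein genes Lsp1beta (1.28 ± 0.17) and Lsp2 (0.85 ± 0.23) and the lipophorin gene apolpp (0.87 ± 0.22). fat-spondin (1.74 ± 0.28) and the perilipin gene Lsd-1 (1.06 ± 0.22) rose as well (adjusted p of these 5 at most 0.0454). Drs, DptB, CecA1, PGRP-SC1a, Lsp2 and apolpp were chosen after their values were seen. The log2 change of Cyp6a17 (5.91 without control 2, 4.15 without control 3) depended on single libraries.

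Some tracheal markers fell in mutant-labelled glands. The scavenger receptor gene emp (-1.88 ± 0.19), the transcription factor gene dysf (-3.70 ± 0.46, adjusted p at most 0.00196) and uif (-0.95 ± 0.26, adjusted p = 0.0492) were lower. The call of uif was lost without control 1 (0.0679), control 3 (0.126), mutant-labelled 1 (0.152) or mutant-labelled 2 (0.166; over all settings 0.00607 to 0.166). Of this list, 0 rose and 3 fell of 17 tested (0 and 4 adjusted over the list alone). As a list, tracheal markers had a camera adjusted p = 0.0373 (adjusted p = 0.869 with an estimated correlation). The call of the tracheal list was lost without control 2 (0.0703), mutant-labelled 1 (0.103) or mutant-labelled 2 (0.0534; over all settings 0.0157 to 0.869). Of wing-patterning genes, 0 rose and 2 fell of 46 tested (0 and 0 adjusted over the list alone). These were sd (-0.73 ± 0.18, adjusted p = 0.0317) and zfh2 (-0.89 ± 0.22, adjusted p = 0.0377). The call of sd was lost without control 1 (0.101), control 3 (0.0916), mutant-labelled 1 (0.123), mutant-labelled 2 (0.130) or mutant-labelled 3 (0.0598; over all settings 0.00312 to 0.130). The call of zfh2 was lost without control 1 (0.0846), control 3 (0.101), mutant-labelled 1 (0.121) or mutant-labelled 2 (0.143; over all settings 0.00589 to 0.143). As a list, wing-patterning genes had a camera adjusted p = 0.0397 (adjusted p = 0.988 with an estimated correlation). The call of the wing-patterning list was lost without control 2 (0.464), mutant-labelled 1 (0.177) or mutant-labelled 2 (0.118; over all settings 0.00355 to 0.988).

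Of glue genes, the main late product of this tissue, 0 rose and 1 fell of 13 tested (0 and 1 adjusted over the list alone). The gene was ng2 (13.3-fold lower, log2 -3.73 ± 0.63, adjusted p = 0.00735). As a list, glue genes had a camera adjusted p = 0.997 (adjusted p = 0.997 with an estimated correlation). Their median was 0.090 and their mean -0.39, with camera downward. Of early ecdysone-response genes, 1 rose and 1 fell of 20 tested (1 and 2 adjusted over the list alone). MsrA rose (1.45 ± 0.23, adjusted p = 0.00581) and Eip63E fell (-2.88 ± 0.60, adjusted p = 0.0171). The call of Eip63E was lost without control 1 (0.0617), control 3 (0.0557), mutant-labelled 1 (0.0572) or mutant-labelled 2 (0.0753; over all settings 4.90e-07 to 0.0753). As a list, early ecdysone-response genes had a camera adjusted p = 0.263 (adjusted p = 0.997 with an estimated correlation). The log2 change of ng2 was -4.35 without mutant-labelled 2.

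wde, which encodes a cofactor of SetDB1, rose 3.40-fold in mutant-labelled glands (10.9 ± 0.595 to 37.0 ± 6.15 CPM, log2 1.76 ± 0.18, adjusted p = 0.000864). Of heterochromatin and chromatin-factor genes, 4 rose and 1 fell of 42 tested (4 and 1 adjusted over the list alone). Beside wde, Nipped-B (1.08 ± 0.24), ADD1 (1.02 ± 0.19) and HP4 (0.91 ± 0.19) rose, and the Polycomb gene Psc fell (-1.19 ± 0.32, adjusted p of these 4 at most 0.0444). The call of Nipped-B was lost without control 2 (0.0516), control 3 (0.0923) or mutant-labelled 2 (0.0798; over all settings 0.000661 to 0.0923). The call of ADD1 was lost without control 1 (0.0539) or mutant-labelled 2 (0.0549; over all settings 0.000160 to 0.0549). The call of HP4 was lost without control 1 (0.0632), control 3 (0.0767), mutant-labelled 1 (0.0816) or mutant-labelled 2 (0.0732; over all settings 0.000587 to 0.0816). As a list, chromatin-factor genes had a camera adjusted p = 0.997 (adjusted p = 0.997 with an estimated correlation). Camera's direction was downward and fry's upward. Of genes of the piRNA pathway, 2 rose and 1 fell of 29 tested (2 and 0 adjusted over the list alone). mael (3.51 ± 0.32) and AGO3 (1.98 ± 0.29) rose (adjusted p at most 0.00430), and armi fell (-0.997 ± 0.27, adjusted p = 0.0450). The call of armi was lost without control 1 (0.132), control 2 (0.0807), mutant-labelled 1 (0.153), mutant-labelled 2 (0.117) or mutant-labelled 3 (0.0875; over all settings 0.00222 to 0.153). As a list, piRNA genes had a camera adjusted p = 0.920 (adjusted p = 0.997 with an estimated correlation). Here too camera's direction was downward and fry's upward. Psc was chosen after its gland value was seen. Over all 42 lists tested in glands, 4 passed with camera, against 11 at an unadjusted p under 0.05. With an estimated correlation 0 passed (lowest adjusted p 0.869, 1 at an unadjusted p under 0.05), and with fry 0 (lowest 0.0528, 9 unadjusted).

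In mutant-labelled wing discs, some transcripts typical of the germline rose, although neither the piRNA nor the ovarian list passed with camera. moon, which directs transcription of piRNA clusters, rose 264-fold (0.188 ± 0.0693 to 49.6 ± 5.65 CPM; log2 8.02 ± 0.20, adjusted p = 1.14e-09). qin and krimp, which encode Tudor-domain proteins of the piRNA pathway, rose 15.9-fold and 12.9-fold (log2 3.99 ± 0.11 and 3.68 ± 0.17, adjusted p at most 1.16e-07). The ovarian translational repressor gene bru1 rose by 6.60 ± 0.47 and bam, which drives germline differentiation, by 3.08 ± 0.20 (adjusted p at most 3.21e-06). Among genes that reached 10 CPM, the steepest rises lay beside moon on the X chromosome: lncRNA:CR43961 (12067200 to 12070139; log2 9.71 ± 0.30) and CG34323 (12070437 to 12071263; log2 9.86 ± 0.26), next to moon itself (12072008 to 12072818, BDGP6). The others were CG43088 (8.89 ± 0.26), CG3251 (8.18 ± 0.39), CG18605 (8.01 ± 0.20), CG11929 (7.98 ± 0.44) and asRNA:CR44237 (7.64 ± 0.26, 81.5% overlapped by Or88a), with adjusted p at most 4.59e-07. The steepest falls were of kek4 (229 ± 5.68 to 0.573 ± 0.137 CPM; -8.65 ± 0.12), CG6912 (-7.74 ± 0.33), mthl8 (-7.48 ± 0.17), ChLD3 (-7.30 ± 0.31), CG40160 (-7.28 ± 0.13), asRNA:CR45600 (-6.99 ± 0.15, 59.4% overlapped by CG3984), CG13458 (-6.54 ± 0.25) and CG14982 (-6.35 ± 0.35; adjusted p at most 4.68e-07). Of 9379 genes tested in discs, 2932 (31.3%) passed, 1502 higher and 1430 lower (3962 at an unadjusted p under 0.05), and 961 of them changed by at least 1 on the log2 scale. The count was 1883 without control library 2, and 1032 when all 12 libraries were fitted together. Single libraries moved the log2 changes of CG34323 (10.80 without control 2, 9.20 without control 3), lncRNA:CR43961 (12.37 without control 3), CG3251 (9.88 without control 1), bru1 (7.30 without control 1, 5.93 without control 3), CG6912 (-8.90 without mutant-labelled 3) and CG14982 (-7.34 without mutant-labelled 1) by over 1.5 times.

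Most cytosolic ribosomal protein genes rose in mutant-labelled discs, and the median of the list was 0.35. Examples were RpS14a (856 ± 61.2 to 1622 ± 220.3 CPM, log2 0.92 ± 0.10), RpLP1 (0.52 ± 0.069), RpS21 (0.52 ± 0.080) and the paralog gene RpL22-like (2.75 ± 0.32, adjusted p of these 4 at most 0.000868). In all, 72 rose and 0 fell of 87 tested (79 and 0 adjusted over the list alone). As a list, ribosomal protein genes had a camera adjusted p = 1.19e-14 (adjusted p = 0.789 with an estimated correlation). Some wing-patterning genes fell, among them the homeobox genes en (114 ± 5.29 to 72.6 ± 6.48 CPM, log2 -0.65 ± 0.079), ap (-0.62 ± 0.079), Dr (-0.62 ± 0.067) and tup (-0.54 ± 0.091, adjusted p of these 4 at most 0.00156). Of that list, 2 rose and 21 fell of 50 tested (2 and 24 adjusted over the list alone). As a list, disc wing-patterning genes had a camera adjusted p = 0.000161 (adjusted p = 0.789 with an estimated correlation). Of replication and cell-cycle genes, 0 rose and 16 fell of 49 tested (0 and 16 adjusted over the list alone). Cdk4 (-0.50 ± 0.064), CycB3 (-0.53 ± 0.059), CycA (-0.38 ± 0.063) and Cdc45 (-0.44 ± 0.072) were among the lower ones (adjusted p at most 0.00147). As a list, replication genes had a camera adjusted p = 0.00189 (adjusted p = 0.789 with an estimated correlation). Of secretory-pathway genes, 0 rose and 10 fell of 40 tested (0 and 7 adjusted over the list alone). Atf6 (-0.60 ± 0.079), the chaperone gene Hsc70-3 (-0.45 ± 0.10) and the translocon gene Sec61alpha (-0.36 ± 0.081) fell, but so did the synaptic SNARE gene Snap25 (-3.73 ± 0.39, adjusted p of these 4 at most 0.00815). As a list, secretory genes had a camera adjusted p = 0.00422 (adjusted p = 0.789 with an estimated correlation). When all 12 libraries were fitted together, ap, CycB3, CycA, Cdc45, Atf6, Hsc70-3 and Sec61alpha no longer passed.

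Some endocycle genes of mutant-labelled discs fell by small amounts. They were dup (-0.40 ± 0.099), Orc1 (-0.37 ± 0.11), Orc2 (-0.35 ± 0.11), Cdk2 (-0.30 ± 0.096) and CycE (-0.28 ± 0.081), with adjusted p at most 0.0405. Of this list, 0 rose and 5 fell of 15 tested (0 and 7 adjusted over the list alone). As a list, endocycle genes had a camera adjusted p = 0.0207 (adjusted p = 0.789 with an estimated correlation). The call of dup was lost without control 2 (0.0535; over all settings 0.00154 to 0.128). The call of Orc1 was lost without control 1 (0.105), control 2 (0.0730), mutant-labelled 1 (0.0813) or mutant-labelled 3 (0.0808; over all settings 0.0132 to 0.404). The call of Cdk2 was lost without control 1 (0.108), control 2 (0.0950), control 3 (0.0617), mutant-labelled 1 (0.0777) or mutant-labelled 3 (0.0918; over all settings 0.0163 to 0.467). The call of CycE was lost without control 1 (0.0694), control 2 (0.0982) or mutant-labelled 1 (0.0564; over all settings 0.0134 to 0.427). Orc2 was chosen after its value was seen. When all 12 libraries were fitted together, dup, Orc1, Cdk2 and CycE did not pass.

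The regulator genes eya (-0.86 ± 0.10), dac (-0.52 ± 0.12), so (-0.48 ± 0.12) and toy (-1.89 ± 0.54) fell in mutant-labelled wing discs, with adjusted p at most 0.0216. The call of so was lost without control 2 (0.0651; over all settings 0.00591 to 0.545). The call of toy was lost without control 2 (0.0822), mutant-labelled 1 (0.0735) or mutant-labelled 2 (0.0860; over all settings 0.0127 to 0.0860). They belong to the homeotic and Polycomb-target list, of which 0 rose and 5 fell of 11 tested (0 and 5 adjusted over the list alone). As a list, Polycomb targets had a camera adjusted p = 0.0207 (adjusted p = 0.789 with an estimated correlation). The call of the Polycomb-target list was lost without mutant-labelled 2 (0.0725; over all settings 0.00666 to 0.789). Of oxidative-phosphorylation genes, 17 rose and 4 fell of 69 tested (17 and 4 adjusted over the list alone). Their median was 0.14, far below the largest rises named here. ATPsynepsilonL (5.85 ± 0.15), ND-20L (2.01 ± 0.38) and ND-39 (0.65 ± 0.076) rose and UQCR-11 fell (-0.87 ± 0.099, adjusted p of these 4 at most 0.00313). As a list, oxidative-phosphorylation genes had a camera adjusted p = 0.0228 (adjusted p = 0.789 with an estimated correlation). The call of the oxidative-phosphorylation list was lost without control 1 (0.0782), control 2 (0.0507) or mutant-labelled 2 (0.1004; over all settings 0.000683 to 0.789). Of heat-shock genes, 0 rose and 4 fell of 15 tested (0 and 7 adjusted over the list alone). They were Hsp83 (-0.67 ± 0.095), stv (-0.57 ± 0.11), DnaJ-1 (-0.55 ± 0.13) and Hsp67Ba (-0.42 ± 0.098, 75.9% overlapped by asRNA:CR43481), with adjusted p at most 0.00952. As a list, heat-shock genes had a camera adjusted p = 0.0262 (adjusted p = 0.789 with an estimated correlation). The call of the heat-shock list was lost without control 3 (0.0603) or mutant-labelled 1 (0.0627; over all settings 0.000280 to 0.789). Of markers of imaginal discs, 1 rose and 7 fell of 19 tested (1 and 8 adjusted over the list alone). wg, for example, fell (-0.42 ± 0.074) and fng rose (0.51 ± 0.088, adjusted p at most 0.00198). As a list, disc markers had a camera adjusted p = 0.0371 (adjusted p = 0.789 with an estimated correlation). The call of the disc-marker list was lost without control 1 (0.0782), mutant-labelled 1 (0.140) or mutant-labelled 2 (0.0729; over all settings 0.0114 to 0.789). When all 12 libraries were fitted together, eya, dac, so, toy, ND-20L, ND-39, Hsp83, stv, DnaJ-1, Hsp67Ba, wg and fng did not pass. The log2 change of toy was -2.55 without mutant-labelled 3.

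Beside moon, qin and krimp, the piRNA genes SoYb (1.33 ± 0.10), mael (1.76 ± 0.17) and the helicase gene vas (2.12 ± 0.50) rose in mutant-labelled discs. aub (-0.82 ± 0.24) and tud (-0.25 ± 0.076) fell (adjusted p of these 5 at most 0.0294). mael, vas, aub and tud were chosen after their disc values were seen. In all, 10 rose and 2 fell of 32 tested (10 and 3 adjusted over the list alone). As a list, disc piRNA genes had a camera adjusted p = 0.0584 (adjusted p = 0.789 with an estimated correlation). With fry their adjusted p was 0.0118. Of other ovarian and germline genes, 6 rose and 6 fell of 19 tested (6 and 6 adjusted over the list alone). As a list, ovarian genes had a camera adjusted p = 0.560 (adjusted p = 0.789 with an estimated correlation). Their median was -0.21 and their mean 0.70, with camera downward and fry upward. Early ecdysone-response genes that fell included Hr4 (-1.995 ± 0.33), Eip93F (-1.99 ± 0.35) and Eip75B (-0.62 ± 0.10, adjusted p of these 3 at most 0.00188), whereas MsrA rose (0.65 ± 0.088, adjusted p = 0.000376). Of that list, 2 rose and 10 fell of 21 tested (2 and 10 adjusted over the list alone). As a list, disc ecdysone-response genes had a camera adjusted p = 0.0703 (adjusted p = 0.789 with an estimated correlation). Among chromatin-factor genes, wde rose 1.76-fold (log2 0.82 ± 0.061), and Psc (-0.76 ± 0.083) and the Trithorax-group gene ash1 (-0.51 ± 0.071) fell (adjusted p at most 0.000469). In all, 7 rose and 12 fell of 43 tested (7 and 13 adjusted over the list alone). As a list, disc chromatin-factor genes had a camera adjusted p = 0.407 (adjusted p = 0.789 with an estimated correlation). Their median was -0.032 and their mean 0.019, with camera downward. When all 12 libraries were fitted together, Hr4, Eip75B, Psc and ash1 did not pass. Over all 43 lists tested in discs, 9 passed with camera, 0 with an estimated correlation (lowest adjusted p 0.789) and 9 with fry. At an unadjusted p under 0.05 these were 15, 0 and 21. Passing with fry but not with camera was not particular to piRNA genes. The lowest fry adjusted p was that of chorion and vitelline genes (0.00965, downward). Cuticle genes (0.0162, upward), other ecdysone-inducible genes (0.0286, downward) and hemocyte markers (0.0451, downward) passed fry alone too. So did genes within 1 Mb of Su(var)3-9 (0.0182, downward) and of egg (0.0197, upward).

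Whether the same genes changed in glands and discs was asked over 8515 genes tested in both. bcd rose in both (5.93 ± 0.81 and 6.01 ± 0.52), as did lncRNA:CR45473 (5.54 ± 0.33 and 5.70 ± 0.27, 24.5% overlapped by tyn) and lncRNA:CR46253 (5.74 ± 0.52 and 5.43 ± 0.20). mir-2279 rose in glands (4.76 ± 0.60) and was at least 59.4-fold higher in discs, and lncRNA:CR44712 was at least 19.2-fold higher in glands and rose in discs (6.07 ± 0.63). These bounds are against controls without a count and a floor of 3 counts over the group. Falls in both tissues were steepest for mthl8 (-6.81 ± 0.41 and -7.48 ± 0.17), CR44383 (-5.85 ± 0.36 and -7.05 ± 0.43), CG1544 (-5.62 ± 0.42 and -6.33 ± 0.29), CG40160 (-5.51 ± 0.37 and -7.28 ± 0.13) and CG43273 (at least 48.7-fold lower in glands, where no mutant-labelled library had a count, and -6.69 ± 0.62 in discs). For these 10 genes the adjusted p was at most 0.00931 in glands and 0.000109 in discs. Of 435 genes past the threshold in both tissues, 355 (81.6%) had the same sign. Of these, 178 rose in both (77.0 if the tissues were independent, Fisher's exact test, two-sided p = 1.11e-30) and 177 fell in both (64.8, p = 2.04e-41). In opposite directions, 53 rose in glands and fell in discs (74.2, Fisher's exact p = 0.00525) and 27 did the reverse (67.2, p = 2.18e-09). Genes are not independent, and across the 8515 genes the changes of the tissues had a Spearman rho of 0.291 and a Pearson r of 0.367. The count of 355 with the same sign was 222 without gland control 1, 222 without gland control 3 and 214 without mutant-labelled gland library 2, and 183 at a log2 change of at least 1 in both. Log2 changes that single libraries moved by over 1.5 times were in glands those of bcd (7.08 without control 1, 5.15 without control 3, less far without mutant-labelled 3), mir-2279 (6.44 without control 3) and lncRNA:CR46253 (6.40 without control 3) and in discs those of bcd (6.80 without control 1), lncRNA:CR44712 (10.23 without control 1, 5.40 without control 3) and CG43273 (-9.25 without mutant-labelled 2).

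**Figure D2:**
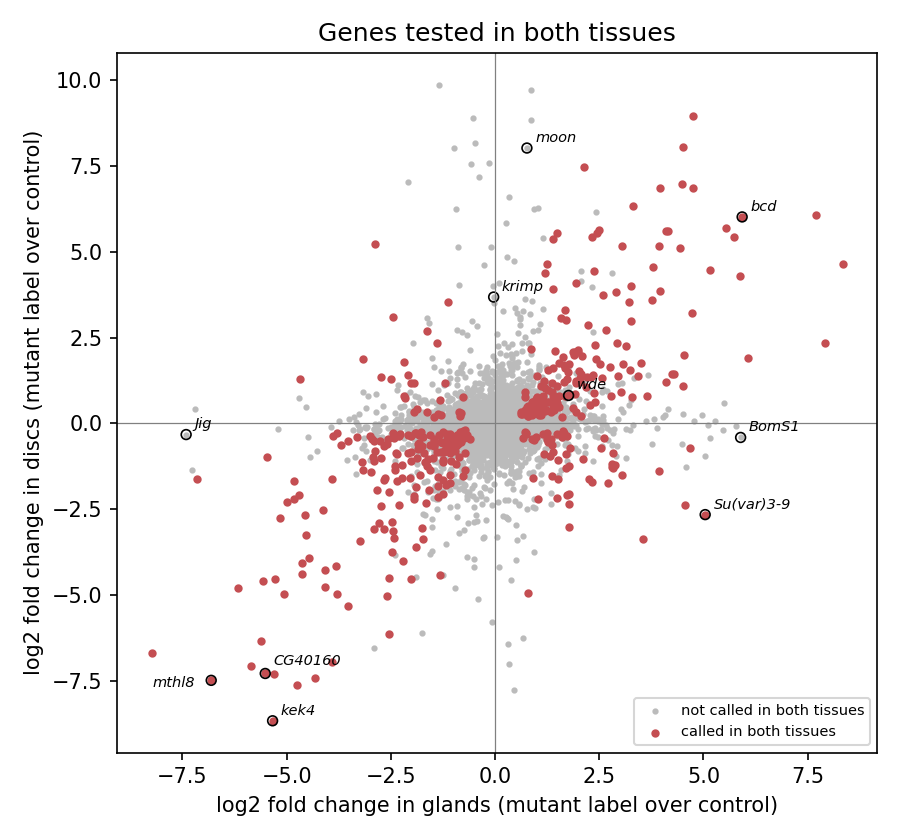
Change of each gene in glands and in discs, log2 of mutant-labelled over control. Each point is 1 of the genes tested in both tissues, red points passed an adjusted p of 0.05 in both, and black circles mark labelled genes. Fits used n = 3 libraries per group.

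The change of a gene was compared between the tissues as the log2 change in discs minus that in glands. Tissue and mRNA enrichment coincide here, and the fit shares its spread between the tissues. It was more positive in discs for CG34323 (11.0001 ± 0.83), CG11929 (9.60 ± 1.66), CG43088 (9.19 ± 0.95), CG18605 (8.78 ± 0.69) and lncRNA:CR43961 (8.65 ± 0.83; adjusted p at most 0.00242). It was more positive in glands for CG6912 (-8.29 ± 0.82), Su(var)3-9 (-7.77 ± 0.32), asRNA:CR45600 (-7.39 ± 0.44), CG14982 (-7.28 ± 0.98) and CG10140 (-7.02 ± 0.70; adjusted p at most 0.000424). The piRNA genes moon (7.08 ± 0.72), qin (3.91 ± 0.42) and krimp (3.56 ± 0.42) rose more in discs, and BomS1 (-6.40 ± 0.70) rose more in glands (adjusted p at most 0.000169), whereas no difference past the threshold was seen for bcd (-0.044 ± 1.25, adjusted p = 0.9999). Other piRNA genes went both ways. SoYb (1.42, adjusted p = 0.00578) was more positive in discs, and AGO3 (-2.86, adjusted p = 0.00138) and mael (-1.85, adjusted p = 0.00553) were more positive in glands. Of 10185 genes tested, the change of 1027 (10.1%) differed, 455 more positive in discs and 572 more positive in glands (2344 at an unadjusted p under 0.05). The count was 676 without disc control 2, 662 without disc control 3 and 667 without mutant-labelled disc library 2, and 1548 with DESeq2. Of the differences given here as past the threshold, single libraries moved by over 1.5 times those of BomS1 (-7.01 without gland control 2, -5.51 without disc control 1), CG11929 (7.91 without gland control 2, 10.29 without gland control 3, 8.99 without gland mutant-labelled 2, 10.94 without gland mutant-labelled 3), CG18605 (8.002 without gland control 2), CG34323 (10.31 without gland control 2, 11.94 without disc control 2), CG43088 (7.95 without gland control 2, 9.81 without gland control 3), moon (6.08 without gland control 2), CG14982 (-6.70 without gland mutant-labelled 2, -8.23 without disc mutant-labelled 1), lncRNA:CR43961 (11.10 without disc control 3) and CG6912 (-9.36 without disc mutant-labelled 3).

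Transposable elements took more reads in both mutant-labelled tissues. In glands their sum rose from 3768 ± 261 to 6615 ± 839 RPM (transposon reads scaled to the gene reads of the library, a ratio of 1.76 and means of 0.377% and 0.662% of gene reads). In discs it rose from 6666 ± 465 to 32655 ± 1928 RPM (a ratio of 4.90, 0.667% and 3.27%). Groups of n = 3 did not overlap (exact permutation test, two-sided p = 0.1 in each tissue, the smallest that 3 against 3 libraries allow). Among single elements, the consensus G6_DM rose most in glands (5.86 ± 0.44), followed by GYPSY_LTR (5.27 ± 0.51), GTWIN_I (5.25 ± 0.50), GTWIN_LTR (4.66 ± 0.49) and MICROPIA_LTR (4.43 ± 0.62; adjusted p at most 1.33e-11). POGON1, left out of this comparison for its month names, was at 4.98 ± 0.48 when these were read as numbers. The value of MICROPIA_LTR rests on control 3, since the other 2 gland controls had 0 counts. Without control 3 no control count is left, so the 8.90 of that fit is set by its prior and is no measured change. IDEFIX_I (-5.15 ± 0.44), IDEFIX_LTR (-4.29 ± 0.44), BLOOD_LTR (-2.27 ± 0.41), BLASTOPIA_I (-2.23 ± 0.39) and Transib4 (-2.20 ± 0.47) fell most in glands (adjusted p at most 7.42e-06). In discs CIRCE (7.71 ± 0.19), GYPSY_LTR (7.67 ± 0.43), GYPSY12_LTR (7.65 ± 0.24), DM1731_I (7.09 ± 0.47) and GYPSY_I (6.98 ± 0.30) rose most (adjusted p at most 6.47e-08). INVADER1_I (-2.44 ± 0.20), Transib5 (-1.94 ± 0.27), IDEFIX_I (-1.85 ± 0.19), INVADER1_LTR (-1.78 ± 0.19) and TART_B1 (-1.64 ± 0.19) fell most in discs (adjusted p at most 3.34e-05), whereas IDEFIX_LTR rose there (1.66 ± 0.19, adjusted p = 6.13e-06; -0.66 relative to the transposon sum). Entries ending in _I and _LTR, such as GYPSY_I and GYPSY_LTR, can be parts of the same retrotransposon. Each is counted and ranked as an element here and below, so counts of elements are not counts of families. In glands 119 of 161 elements tested passed, 97 higher and 22 lower, and in discs 150 of 168, 139 higher and 11 lower. Relative to the summed transposon reads, the split was 66 higher and 40 lower in glands and 69 and 72 in discs. Elements whose log2 change single libraries moved by over 1.5 times were in glands G6_DM (6.47 without control 2), GYPSY_LTR (6.07 without control 2) and GTWIN_LTR (5.28 without control 2) and in discs GYPSY_LTR (9.18 without control 1) and DM1731_I (7.78 without control 3).

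**Figure D3:**
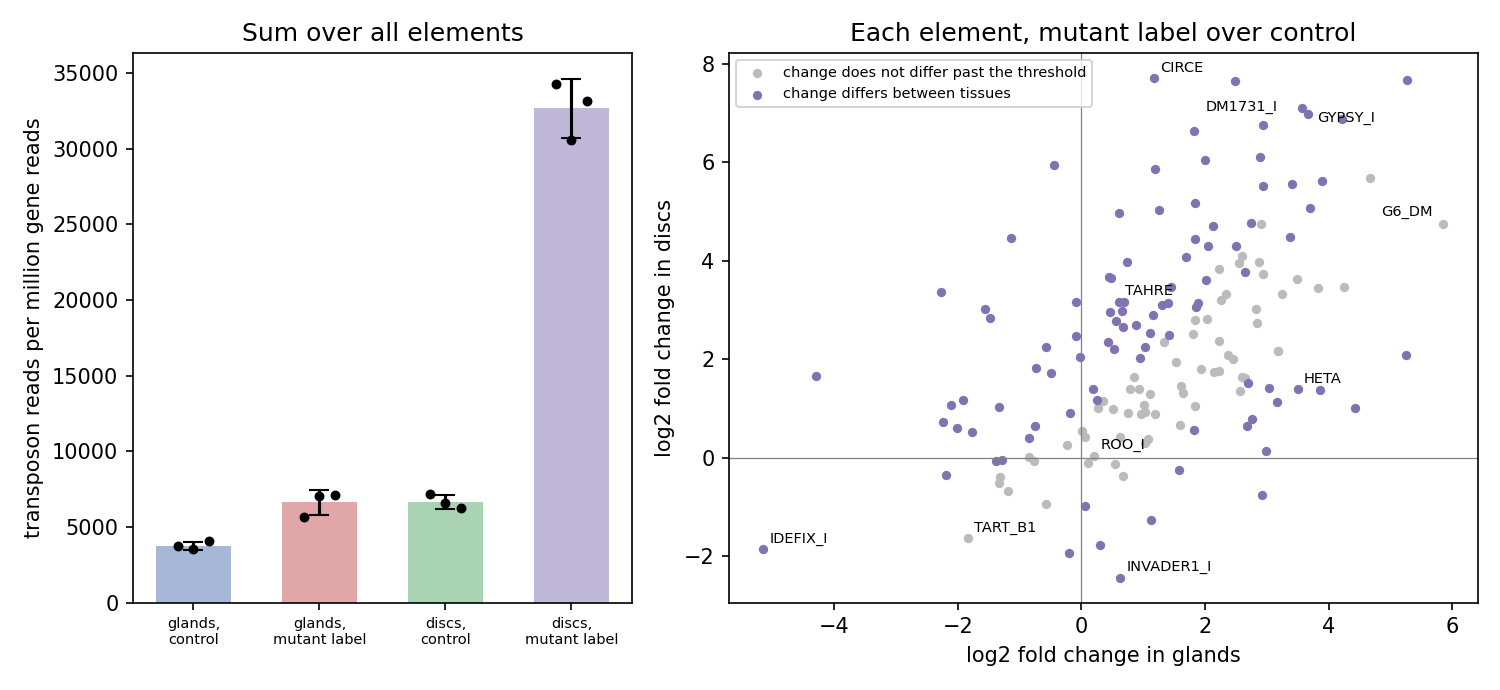
Reads of transposable elements. Left, summed transposon reads in RPM of gene reads; points are libraries, bars means and error bars SD over n = 3 libraries per group. Right, log2 change of each element tested in both tissues, in glands and in discs, relative to gene reads; purple points are elements whose change differed between the tissues at an adjusted p under 0.05.

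Well-studied elements did not move alike. Of the telomeric retrotransposons, HETA rose in glands (3.50 ± 0.42, adjusted p = 4.93e-15) and, relative to gene reads, in discs (1.39 ± 0.23, adjusted p = 0.000158), where it fell relative to the transposon sum (-0.95). TAHRE rose in discs (3.17 ± 0.17, adjusted p = 1.08e-08) and did not pass in glands (0.61 ± 0.39, adjusted p = 0.144). TART_B1 fell in both (-1.83 ± 0.36 and -1.64 ± 0.19; adjusted p at most 6.86e-06). TART-A rose in both (2.22 ± 0.41 and 2.37 ± 0.86, in discs -0.043 relative to the transposon sum). Disc control 3 held 3122 reads of TART-A and the other disc controls 213 and 189. With 1 library left out the disc value was 1.71 to 4.59, the latter without control 3. The call of TART-A in discs was lost without control 1 (0.0853) or mutant-labelled 1 (0.118; over all settings 1.62e-28 to 0.965). DM1731_I rose in both (3.56 ± 0.37 and 7.09 ± 0.47), as did the non-telomeric MDG1_I (1.61 ± 0.39 and 1.46 ± 0.18), whose disc value relative to the transposon sum was -0.87 and whose gland call was lost on that scale (0.79, adjusted p = 0.0639). MDG1_LTR rose in glands (1.13 ± 0.44, adjusted p = 0.0152; 0.27 relative to the transposon sum, adjusted p = 0.526) but fell in discs (-1.26 ± 0.20, adjusted p = 0.000126). The call of MDG1_LTR in glands was lost without control 2 (0.0794; over all settings 0.00290 to 0.526). COPIA_DM_I rose in both (0.79 ± 0.31 and 1.39 ± 0.19; -0.14 and -0.93 relative to the transposon sum). The call of COPIA_DM_I in glands was lost without control 1 (0.0589), control 3 (0.0749) or mutant-labelled 2 (0.0772; over all settings 0.00105 to 0.683). COPIA2LTR_DM fell in glands (-1.62 ± 0.61, adjusted p = 0.0114; -0.98 without control 1 and -2.25 without mutant-labelled 1). The call of COPIA2LTR_DM in glands was lost without control 1 (0.227), mutant-labelled 2 (0.0656) or mutant-labelled 3 (0.0797; over all settings 0.00116 to 0.227). DM297_I rose in both (2.22 ± 0.40 and 1.75 ± 0.20; in discs -0.56 relative to the transposon sum), and DM297_LTR in glands alone (2.98 ± 0.42, adjusted p = 2.09e-11; in discs 0.13 ± 0.21, adjusted p = 0.556; -2.18 relative to the transposon sum, adjusted p = 7.42e-06). DM412_I rose in discs (2.03 ± 0.20; -0.29 relative to the transposon sum) and did not pass in glands (-0.024 ± 0.40, adjusted p = 0.957; -0.94 relative to the transposon sum, adjusted p = 0.0197). ROO_I passed in neither (0.21 ± 0.34, adjusted p = 0.584; 0.040 ± 0.17, adjusted p = 0.820), but fell in discs relative to the transposon sum (-2.27, adjusted p = 1.44e-06), whereas ROO_LTR fell in glands (-1.38 ± 0.38, adjusted p = 0.000590) and did not pass in discs (-0.078 ± 0.15, adjusted p = 0.637; -2.40 relative to the transposon sum, adjusted p = 7.36e-07). R1_DM, an element of ribosomal DNA, rose in glands (2.76 ± 0.41, adjusted p = 1.47e-10) and in discs (0.78 ± 0.28, adjusted p = 0.0225; -1.55 relative to the transposon sum). The call of R1_DM in discs was lost without control 1 (0.0879) or mutant-labelled 1 (0.0921; over all settings 0.000137 to 0.0921). R2_DM, which inserts into ribosomal DNA, rose in glands (1.57 ± 0.41, adjusted p = 0.000252; 2.43 without control 3) and did not pass in discs (-0.25 ± 0.23, adjusted p = 0.313). Relative to the transposon sum R2_DM did not pass in glands (0.68, adjusted p = 0.166) and fell in discs (-2.57, adjusted p = 4.18e-06). Of 159 elements tested in both tissues, 91 rose in both, 4 fell in both, 2 rose in glands and fell in discs, 11 did the reverse, and 30 rose in discs without passing in glands. The change of 97 of 168 elements differed between the tissues, 79 more positive in discs and 18 more positive in glands, or 42 and 58 relative to the transposon sum. By difference, CIRCE (6.48 ± 0.45), IDEFIX_LTR (5.88 ± 0.50) and BLOOD_LTR (5.55 ± 0.51) were among those more positive in discs. DM297_LTR (-2.91 ± 0.39) and HETA (-2.19 ± 0.40) were among those more positive in glands (adjusted p at most 9.08e-05). The log2 change of R1_DM (4.06 without control 3) in glands and of DM1731_I (7.78 without control 3) in discs depended on single libraries.

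Pericentromeric regions and chromosome 4, both rich in H3K9 methylation, were compared with the rest of the genome. Near the centromeres, CG3635 rose (6.59 ± 0.36) and CG17698 (-5.56 ± 0.33), CG40160 (-5.51 ± 0.37) and Alg-2 (-3.003 ± 0.20) fell in glands (adjusted p at most 0.000139). In discs Marf1, an RNA regulator of oogenesis (5.53 ± 0.086), lncRNA:CR46123 (6.97 ± 0.18) and lncRNA:CR42646 (5.42 ± 0.14) rose and CG40160 fell (-7.28 ± 0.13; adjusted p at most 1.19e-09). On chromosome 4, CG11155 rose (4.97 ± 0.29) and CG31998 (-2.91 ± 0.25) and Crk (-2.03 ± 0.23) fell in glands (adjusted p at most 0.00133). Of 267 pericentromeric genes tested in glands, 32.6% passed against 12.6% of the genes elsewhere (31 higher and 56 lower; Fisher's exact test, two-sided, adjusted over 8 regions, adjusted p = 7.78e-16). In discs it was 47.6% against 30.8% (57 higher and 70 lower, adjusted p = 1.56e-07). On chromosome 4, 26.7% of 86 genes passed in glands against 13.0% elsewhere (11 higher and 12 lower, adjusted p = 0.00167), and 36.8% of 87 in discs against 31.2% (adjusted p = 0.394). Genes of the X chromosome passed less often in glands (9.17% against 13.9%, adjusted p = 7.60e-07) and those of 2R more often (15.3% against 12.6%, adjusted p = 0.00397), and no other arm passed in either tissue. Neighbouring genes are not independent, so the p-values of these Fisher tests are too small. Strain and genotype also coincide, so the shares cannot be credited to the mutations. As a list, pericentromeric genes of glands had a camera adjusted p = 0.0694 (adjusted p = 0.988 with an estimated correlation). As a list, pericentromeric genes of discs had a camera adjusted p = 0.417 (adjusted p = 0.789 with an estimated correlation). In discs their median was -0.037 and their mean 0.20, with camera downward. As a list, chromosome 4 genes of glands had a camera adjusted p = 0.116 (adjusted p = 0.997 with an estimated correlation). Adjusted over the list alone, 37 pericentromeric genes rose and 71 fell in glands and 59 and 72 in discs, and 12 and 17 on chromosome 4 in glands.

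**Figure D4:**
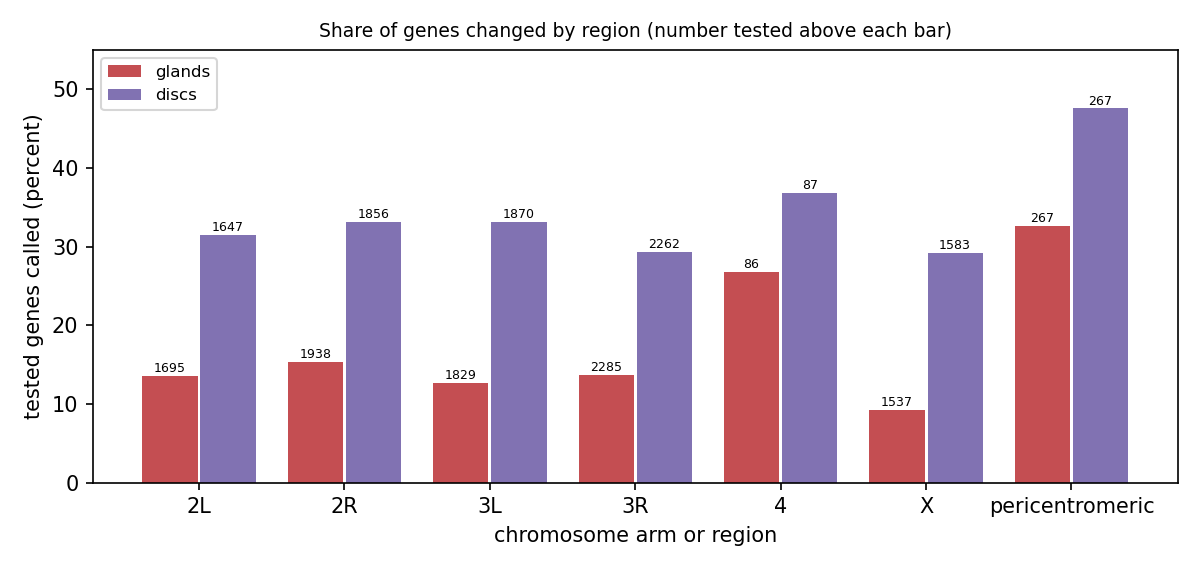
Share of tested genes past an adjusted p of 0.05 on each chromosome arm, on chromosome 4 and in the pericentromeric regions, in glands and in discs. Numbers above the bars are genes tested, from fits with n = 3 libraries per group.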

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

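The weighing tests of Su(var)3-9 in glands, of shared changes and of the germline genes that rose in discs, and the refits of all 62 differing genes without single libraries were chosen only after those results were seen, whereas the interaction tests and the counts under other splits were planned.

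The changes of 1027 of 10185 genes and 97 of 168 transposable elements differed between glands and discs by the interaction test. Among the 139 genes that the naming rule gave, 62 differed, 33 with the more positive change in discs and 29 in glands; values here are the log2 change in discs minus that in glands, with adjusted p from 4.15e-08 to 0.0457. More positive in discs were CG34323 11.0001, CG11929 9.60, CG43088 9.19, CG18605 8.78, lncRNA:CR43961 8.65, CG3251 8.54, lncRNA:CR45043 7.52, moon 7.08, Jig 7.01, asRNA:CR44237 6.73, bru1 6.18, phu 5.82, GluRIIC 5.42, ATPsynepsilonL 5.38, bam 4.58, Marf1 3.96, qin 3.91, ng2 3.72, TwdlM 3.68, krimp 3.56, dysf 3.03, lncRNA:CR42646 3.02, Eip63E 2.76, Alg-2 2.53, lncRNA:CR46123 2.39, CG31998 2.33, emp 2.22, Crk 1.99, Atf6 1.89, SoYb 1.42, UQCR-11 1.12, Dad 0.81 and knk 0.67. More positive in glands were CG6912 -8.29, Su(var)3-9 -7.77, asRNA:CR45600 -7.39, CG14982 -7.28, CG10140 -7.02, CG3635 -6.50, BomS1 -6.40, BomS2 -5.90, alpha-Est1 -5.71, BomBc1 -5.58, BomS3 -5.31, Cyp12d1-p -4.88, CG11155 -4.80, Snap25 -4.73, CG13458 -3.70, kek4 -3.38, AGO3 -2.86, Swim -2.42, fat-spondin -2.41, mael -1.85, CG40160 -1.84, Pxn -1.77, Grik -1.70, Lsd-1 -1.67, TwdlE -1.21, Cdk4 -1.12, wde -1.03, MsrA -0.88 and HP4 -0.74. Among 41 named elements, 27 differed (adjusted p from 3.21e-10 to 0.0329). More positive in discs were CIRCE 6.48, IDEFIX_LTR 5.88, BLOOD_LTR 5.55, GYPSY12_LTR 5.10, DM1731_I 3.45, GYPSY_I 3.24, IDEFIX_I 3.21, COPIA2I_DM 3.12, DMRT1B 3.10, BLASTOPIA_I 2.89, TAHRE 2.48, GYPSY_LTR 2.30, DM412_I 2.01, DMRT1C 1.95, Transib4 1.75, ROO_LTR 1.22 and DMRT1A 1.06. More positive in glands were MICROPIA_LTR -3.47, GTWIN_I -3.27, INVADER1_I -3.14, DM297_LTR -2.91, MDG1_LTR -2.48, HETA -2.19, INVADER1_LTR -2.19, R1_DM -2.03, R2_DM -1.86 and Transib5 -1.81. The call of DMRT1A was lost without gland control 2 (0.0577), gland control 3 (0.0863), gland mutant-labelled 1 (0.0696), gland mutant-labelled 2 (0.0600), disc control 3 (0.0641) or disc mutant-labelled 3 (0.0557; over all settings 0.00933 to 0.552). The call of GYPSY_LTR was lost without gland control 2 (0.131) or disc control 2 (0.0507; over all settings 0.00245 to 0.347). By over 1.5 times as a fold, single libraries moved the differences of the genes BomS1 (-7.01 without gland control 2, -5.51 without disc control 1), CG11929 (7.91 without gland control 2, 10.29 without gland control 3, 8.99 without gland mutant-labelled 2, 10.94 without gland mutant-labelled 3), CG18605 (8.002 without gland control 2), CG34323 (10.31 without gland control 2, 11.94 without disc control 2), CG43088 (7.95 without gland control 2, 9.81 without gland control 3), asRNA:CR44237 (5.70 without gland control 2, 7.51 without gland control 3), moon (6.08 without gland control 2), ATPsynepsilonL (4.26 without gland control 2), ng2 (4.36 without gland mutant-labelled 2), CG14982 (-6.70 without gland mutant-labelled 2, -8.23 without disc mutant-labelled 1), CG13458 (-4.32 without gland mutant-labelled 2, -2.44 without gland mutant-labelled 3), bam (5.76 without gland mutant-labelled 2), CG3251 (10.30 without disc control 1), bru1 (6.90 without disc control 1, 5.57 without disc control 3), lncRNA:CR43961 (11.10 without disc control 3), phu (5.23 without disc mutant-labelled 1), Cyp12d1-p (-5.56 without disc mutant-labelled 2) and CG6912 (-9.36 without disc mutant-labelled 3). Among elements they moved those of GYPSY_LTR (1.54 without gland control 2, 3.83 without disc control 1), GYPSY12_LTR (4.47 without gland control 2), DM1731_I (4.19 without disc control 3), COPIA2I_DM (2.25 without gland control 1), DM412_I (1.41 without gland control 3), MICROPIA_LTR (-8.38 without gland control 3), GTWIN_I (-2.55 without disc control 1), R1_DM (-3.37 without gland control 3) and R2_DM (-2.77 without gland control 3). The -8.38 of MICROPIA_LTR is set by the prior of the fit and is no measured difference, since gland controls 1 and 2 held 0 counts. Of the 62 genes, 7 lost their call without at least 1 library. That of Grik was lost without gland control 1 (0.0617), gland control 3 (0.0525), disc control 1 (0.0543), disc control 3 (0.113), disc mutant-labelled 1 (0.0652) or disc mutant-labelled 2 (0.0587); with all or all but 1 library its adjusted p was 0.00191 to 0.113. That of HP4 was lost without gland control 1 (0.0811), gland control 3 (0.0854), gland mutant-labelled 1 (0.0953), gland mutant-labelled 2 (0.0828), disc control 1 (0.159), disc control 2 (0.0863), disc control 3 (0.112), disc mutant-labelled 1 (0.0824), disc mutant-labelled 2 (0.105) or disc mutant-labelled 3 (0.151); with all or all but 1 library its adjusted p was 0.0190 to 0.159. That of knk was lost without gland control 1 (0.0621), gland mutant-labelled 1 (0.0704), disc control 1 (0.0728), disc control 2 (0.0632), disc mutant-labelled 1 (0.0558) or disc mutant-labelled 3 (0.0686); with all or all but 1 library its adjusted p was 0.0245 to 0.0728. That of Dad was lost without gland control 1 (0.0674), gland control 2 (0.0522), gland mutant-labelled 1 (0.0903), gland mutant-labelled 2 (0.0791), disc control 1 (0.0698), disc control 2 (0.0985), disc control 3 (0.0737), disc mutant-labelled 1 (0.0583), disc mutant-labelled 2 (0.0724) or disc mutant-labelled 3 (0.0898); with all or all but 1 library its adjusted p was 0.00984 to 0.0985. That of CG13458 was lost without gland control 1 (0.0804), gland control 3 (0.0690), gland mutant-labelled 1 (0.0805), gland mutant-labelled 3 (0.344), disc control 1 (0.0915), disc control 2 (0.0714), disc control 3 (0.0969), disc mutant-labelled 1 (0.0936), disc mutant-labelled 2 (0.104) or disc mutant-labelled 3 (0.0805); with all or all but 1 library its adjusted p was 0.0127 to 0.344. That of TwdlM was lost without gland control 1 (0.0617) or gland control 3 (0.143); with all or all but 1 library its adjusted p was 0.00576 to 0.143. That of MsrA was lost without disc control 1 (0.0981), disc control 2 (0.115), disc control 3 (0.0995), disc mutant-labelled 1 (0.0662), disc mutant-labelled 2 (0.131) or disc mutant-labelled 3 (0.109); with all or all but 1 library its adjusted p was 0.0155 to 0.131. Relative to the transposon sum the differences of ROO_LTR (-0.11, adjusted p = 0.745), DMRT1A (-0.24, adjusted p = 0.552), DM412_I (0.66, adjusted p = 0.134), DMRT1C (0.60, adjusted p = 0.128), GYPSY_LTR (0.99, adjusted p = 0.347) and Transib4 (0.41, adjusted p = 0.392) did not pass, the first 2 with the direction turned.

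Of 100 splits drawn from 200 possible ones, the real one included, 2 gave at least as many genes (1027, highest of the others 1248) and 4 at least as many elements (97, highest of the others 117) with a differing change. At first 60 splits had been drawn, of which 2 and 3 gave as many, and the number was raised after that was seen. For elements the first draw did not reach a share under 0.05, so chance is not excluded for them. All the high counts belong to a structure of the samples: 14 of the other splits keep the disc groups whole (up to 1248 genes and 117 elements), 10 keep the gland groups whole (up to 710 and 28) and 75 keep neither (up to 25 and 0). Splits that mix the groups of a tissue take away its genotype effect. They therefore test for any genotype effect, and cannot decide whether the effect differs between tissues, for genes or for elements. Within a tissue only 10 splits exist, too few for a share under 0.05. In glands the real split gave 1243 genes and 119 elements, in discs 2932 and 150, each in 1 of 10 splits, and the highest of the other splits gave 0 in every case. For gene lists, 10 of 10 splits in glands gave at least the real 4 lists (highest of the others 14) and 8 of 10 in discs at least the real 9 (highest of the others 14), so the number of lists past the threshold does not set the real split apart.

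Su(var)3-9 was higher in mutant-labelled glands and lower in mutant-labelled discs. Swapped labels of the gland groups are argued against by the genes that passed in both tissues with a disc change of at least 4 on the log2 scale, of which 96.6% (56 of 58) had the same sign in glands. Reads of the overlapping eIF2gamma are argued against by its own gland change of 0.11, and a rise of the whole region by the 26 other tested genes within 50 kb, whose median was -0.0089 with 0 higher and 2 lower past the threshold. What remains open, and was not tested, is the source of the transcript in mutant-labelled glands, for which the allele, an added copy in the stock or a genotype other than the label are candidates. No biological explanation beyond the tissue itself was tested.

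Many genes changed the same way in both tissues. Segments within 1 Mb of egg or Su(var)3-9 are argued against as the main reason. Of the 355 shared genes 8 lay there, an odds ratio of 0.522 against other genes (95% interval 0.222 to 1.05, Fisher's exact test, two-sided p = 0.0756). Longer linked segments stay open, since the test reaches no further than 1 Mb. Strain background elsewhere in the genome cannot be told apart from the mutations, because strain and genotype coincide in every library. A total of 31 genes changed by at least 4 in both tissues, 14 higher and 17 lower, which a difference between strains could give as well as loss of H3K9 methylation.

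Some germline genes, moon and qin among them, rose in mutant-labelled discs. The summed CPM of 9 of 11 germ-cell markers fell from 18.4 ± 1.22 to 13.3 ± 1.48, a ratio of 0.721, but vas rose (0.242 to 1.06 CPM) and aub fell (4.16 to 2.36), 6 markers were tested, and 1 of these rose and 1 fell past the threshold. Since the markers are low, the list was written after the values were seen and tud was dropped from it because discs express it highly (556 to 467 CPM; the ratio with it is 0.835), a small share of germ cells stays open. A larger copy number of elements in the mutant strain also stays open for the transposons that accompany these genes, because copies can differ in the tissue that transcribes them, and the change of 97 elements differed between the tissues. Derepression of these genes by the mutations may be a candidate explanation, with no test here that separates it from these. CG34323 and lncRNA:CR43961, which lie beside moon on the X chromosome, rose more than moon in discs. Whether the rise of moon belongs to its segment rather than to germline genes was not tested.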

How the results depend on the processing

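Added after the data were seen were month names read back as numbers, limma-voom for elements, and gland counts thinned to the shallowest library; a pseudocount alternative was planned for TPM alone and was not run. Of 2428 checks of named genes, 2310 kept their call and any called direction, 86 lost and 32 gained a call and 0 reversed. The 42 checks of regions all kept theirs. Named elements and lists were less stable. Of 1532 checks of elements, 1442 kept theirs, 40 lost and 28 gained a call and 22 reversed. Of 280 checks of described lists, 225 kept theirs, 40 lost and 15 gained a call. The number of genes in glands was 1013 to 1732 over the alternatives in which all gland libraries were kept, apart from 2360 with all 12 libraries fitted together (1186 of the 1243 kept with the same sign), and 705 to 1512 with 1 library left out; in discs it was 2923 to 3154, apart from 1032 with all 12 together (986 of the 2932 kept) and 961 at a log2 change of at least 1, and 1883 to 2984 with 1 library left out. For the difference between tissues it was 1548 with DESeq2 and 662 to 1366 with 1 library left out, and for genes with the same sign in both tissues it was 183 at a log2 change of at least 1 and 214 to 424 with 1 left out, against 355. Lists passing were 0 in glands and 0 in discs with an estimated correlation, 0 in glands with fry, and 3 to 8 in glands and 7 to 12 in discs with 1 library left out. A fit to all 12 libraries shares its spread between the tissues, whose biological coefficients of variation were 0.292 in glands and 0.102 in discs. Such sharing lowers the spread set for glands and raises that for discs. The difference between tissues rests on the same fit, so it may understate the spread of glands. Leaving out a library leaves fewer libraries, and the cause of the other shifts was not tested.

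With transposon totals as library sizes, elements reversed in glands, in discs and in the difference between tissues; the cause is the scaling itself, since a change is then relative to the mean of elements that rose. Values were in glands COPIA_DM_I -0.14 and COPIA_DM_LTR -0.067; in discs BLASTOPIA_I -1.57, COPIA_DM_I -0.93, COPIA_DM_LTR -0.69, DM297_I -0.56, DM297_LTR -2.18, DM412_I -0.29, DMRT1B -1.27, GTWIN_I -0.22, HETA -0.95, IDEFIX_LTR -0.66, MDG1_I -0.87, MICROPIA_LTR -1.33, R1-2_DM -0.50, R1_DM -1.55, ROO_I -2.27 and TART-A -0.043; and in discs minus glands COPIA_DM_I -0.79, DMRT1A -0.24, ROO_LTR -0.11 and TART_B1 -1.20.

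Deviations of libraries with equal replicate numbers correlated by 0.00853, 0.363 and 0.382 in glands and 0.120, -0.0687 and 0.150 in discs. Those with unequal numbers correlated by -0.436 to 0.194 in glands and -0.211 to 0.112 in discs. Pairing by replicate number is therefore not excluded, above all in glands, and the main fits use none. With replicate number as a block, 1570 genes passed in glands, 3007 in discs and 1162 for the difference, 121, 149 and 102 elements, and 4 and 12 lists. At the depth of the shallowest gland library 1013 genes passed. In a simulation with a smaller share of changed genes than was called, a 2-fold change was recovered in 25.4% of gland genes. An absent call in glands is therefore no sign that a gene is unchanged.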

Other observations

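Reading the month names back as numbers, and which lists to describe, were chosen only after the data were seen. In mutant-labelled discs, cuticle protein genes moved both ways: 15 rose and 6 fell of 38 tested (16 and 6 adjusted over the list alone). As a list, cuticle genes had a camera adjusted p = 0.0584 (adjusted p = 0.789 with an estimated correlation). There were rises of TwdlM (3.81 ± 0.26), Lcp65Ag3 (6.20 ± 0.75, 8.13 without control 1, 100% overlapped by asRNA:CR46005) and TwdlE (1.63 ± 0.13, 71.9% by lectin-28C) and a fall of Cpr67Fb (-3.71 ± 0.47, 85.1% by asRNA:CR45171; adjusted p at most 0.000212). Of hemocyte markers, 1 rose and 7 fell of 17 tested (1 and 7 adjusted over the list alone). As a list, hemocyte markers had a camera adjusted p = 0.0591 (adjusted p = 0.789 with an estimated correlation). There were falls of Hml (-1.55 ± 0.18), Pxn (-1.49 ± 0.19) and NimC1 (-3.80 ± 0.70; -6.16 without mutant-labelled 3) and a rise of Tig (0.81 ± 0.19; adjusted p at most 0.00851). Of JNK and regeneration genes, 8 rose and 4 fell of 25 tested (9 and 4 adjusted over the list alone). As a list, JNK genes had a camera adjusted p = 0.215 (adjusted p = 0.789 with an estimated correlation). Rises were those of scaf (1.60 ± 0.10), Gadd45 (1.42 ± 0.13) and the phosphatase gene puc (0.64 ± 0.11) and a fall of Swim (-2.28 ± 0.30; adjusted p at most 0.00174). The other falls of that list, named after their values were seen, were of upd3 (-1.19 ± 0.39), Ance (-0.33 ± 0.065) and Socs36E (-0.30 ± 0.070; adjusted p at most 0.0389). With all 12 libraries fitted together, Tig and puc did not pass.

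Read back as numbers, the month names let POGON1 and DM412B_LTR be fitted in glands and DM412_LTR in discs. POGON1 then rose in glands (4.98 ± 0.48, adjusted p = 4.55e-22) and DM412_LTR in discs (4.07 ± 0.27, adjusted p = 6.33e-08), and DM412B_LTR did not pass in glands (0.37 ± 0.56, adjusted p = 0.548). In the tissue that had no month names for them, POGON1 rose in discs (3.65 ± 0.18, adjusted p = 6.74e-09) and DM412_LTR in glands (1.88 ± 0.47, adjusted p = 0.000133), and DM412B_LTR did not pass in discs (-0.51 ± 0.30, adjusted p = 0.123).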
